A study of Mus musculus with 4 samples.

How the data were processed

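Testis RNA was profiled in 2 wild-type and 2 Fam170a knockout libraries. Per the labels' protocols, total RNA from adult testes was extracted with Trizol, poly(A) RNA was captured on beads, and full-length cDNA was made from it, ligated to adaptors and amplified by PCR. The submitters' processing notes list fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.1 and RSEM without a version, and give neither their order nor the role of each. The genome build, the annotation, the strandedness of counting and the treatment of reads that match several genes are not given in the sources used here. The deposited table holds read counts of 22274 Ensembl genes as whole numbers, with different totals per library and no normalization by the authors visible in the values. Whether these counts are rounded RSEM estimates is not given. Because reads without molecular identifiers are not independent molecules, the intervals and floors given here cover counting error only.

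Columns were matched to samples by genotype and replicate number, since the column names carry letters that the labels do not explain. Groups were taken from the sample titles. The genotype label of KO replicate 2 names Fam171a, and Fam170a counts were therefore reported in every library first. The table holds no comparison by the authors, so the planned comparison with their fold changes was not made. Gene symbols, chromosomes and positions came from GENCODE M21 on GRCm38 and a table of gene names, which matched 22219 of the 22274 identifiers and left 55 without a symbol, and 21743 were protein-coding in that annotation. Genes without a symbol there kept the one written in the deposited table, and a list entry found neither by symbol nor by synonym was looked up by that symbol. Every line of the table named a gene.

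Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15636 genes and set aside 6638. Libraries were scaled with TMM factors of 1.00, 1.08, 0.987 and 0.940 for WT replicates 1 and 2 and KO replicates 1 and 2, and CPM values used the scaled library sizes. The quasi-likelihood test was two-sided with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. For a called gene with 1 to 3 counts in a group, the ratio of summed rates is given with an exact 95% Clopper-Pearson interval, and for 0 counts a lower bound against 3 counts over the group.

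Replicates were compared before averaging. Across genes, Pearson's r of log2 CPM, with 1 added to each CPM, was 0.991 between WT libraries and 0.996 between KO libraries, and a chi-square statistic per degree of freedom of 44.3 and 10.4 showed that neither pair was a single library deposited under both names. Between genotypes r was 0.985 to 0.991. By the chi-square statistic the WT libraries differed more from each other than WT replicate 1 did from KO replicate 1 (35.7) or KO replicate 2 (30.8). For WT replicate 2 the statistic was 39.0 against KO replicate 1 and 62.1 against KO replicate 2.

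Most genes named in the text were fixed by rule before the data were examined, as were 28 gene lists, the test and the alternatives. Rpl10a, Catspere1, Catspere2, the overlapping genes Lamp1 and Sh3gl2, and further genes under other observations lay outside that rule. The rule took Fam170a, Fam170b, Fam171a1, Fam171a2 and Fam171b always. It then took the 12 largest rises and 12 largest falls in log2 fold change among genes past the threshold whose KO libraries both lay above or both below both WT libraries. These had to have a mean of at least 1 CPM and a symbol that is not a predicted or clone name. It added up to 4 members per list with the smallest p and the 5 most abundant genes. The lists held 522 entries, of which 520 were found in the annotation. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 28 lists, and again with an estimated correlation and with fry. The preset correlation makes camera more permissive than the estimate from 4 libraries. With the estimate, most lists shared an adjusted camera p of 0.789, so that value does not rank them. Their unadjusted camera p ran from 0.0825 for mitochondrially encoded and 0.0865 for Y-linked genes to 0.677 for testis histone variants.

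Alternatives were DESeq2 size factors, upper quartile factors or total counts in place of TMM, no filter beyond a count in any library, a filter of 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, a block on the replicate number, leaving out each library in turn, and a threshold of 0.01. A fit without 1 library takes the spread from the other genotype's pair, and assumes that the lone library varies like it. For DESeq2 and limma-voom the lists were tested with camera on signed z-scores made from their p-values. The DESeq2 test left 3032 adjusted p-values undefined. With 2 libraries per genotype neither a test for outlying libraries nor a count over other splits of the samples was made.

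The tests were tested on simulated data drawn for the 15636 genes of the comparison of KO with WT, in which 100 genes were changed 2-fold and 100 were changed 4-fold. edgeR recovered 75% of the former and 100% of the latter with 8 false calls, DESeq2 69% and 98% with 13, and limma-voom 72% and 99% with 9. The changed genes all had an expected count above 30. Each simulated gene took its spread from the trend over genes of its level and had none of its own. A simulated list of 20 genes shifted by 0.7 on the log2 scale was called by camera at the preset correlation, whereas its adjusted p was 0.261 with an estimated correlation and 0.0829 with fry, and 0 of 30 random lists were called by camera or fry. All genes were drawn independently, so the simulated lists held no correlation between genes. Estimates in the real lists ran from -0.06 for cholesterol synthesis to 0.98 for protamines and transition proteins. The 0 of 30 therefore does not show how often camera calls correlated lists falsely. The count of neighbouring genes was tested on simulated data too, with a permutation p of 0.967 for a random set and 1.0e-04 for a set with planted groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.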

Results

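Poly(A) RNA from adult mouse testis was sequenced from wild-type (WT) mice and from mice in which Fam170a had been knocked out (KO), with 2 libraries per genotype. The comparison asked which transcripts differ in the testis without Fam170a, a gene that the series studies for its part in spermiogenesis, the stage at which round haploid spermatids are remodelled into sperm. Total counts were 26029374 for WT replicate 1, 35494303 for WT replicate 2, 34740160 for KO replicate 1 and 41684437 for KO replicate 2. Between 18135 and 18544 genes had at least 1 count in a library, and the 5 genes most abundant over all 4 libraries took 2.08% to 2.27% of each library's counts. Over all 4 libraries the highest mean levels belonged to mt-Co1, Odf2, Akap12, Pabpc1 and Atp8b3, none of which passed the test between genotypes. No label says whether the libraries of a genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical. Values below are CPM (counts scaled to a common library size) as mean ± SD with n = 2 per genotype, and fold changes are KO over WT on the log2 scale with their standard error (SE).

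Fam170a transcripts were nearly lost from both KO libraries. WT libraries held 2240 and 3510 Fam170a counts and each KO library held 1 count, so that mean CPM was 88.9 ± 4.08 in WT and 0.0274 ± 0.00258 in KO. The log2 fold change was -11.49 ± 0.19 (SE; edgeR adjusted p = 4.24e-05). Summed over each genotype, the counts of 5750 and 2 gave a rate 3286-fold lower in KO, with an exact 95% interval of 909 to 27141 that covers counting error only. Fam170a (ENSMUSG00000035420) is a protein-coding gene on the forward strand of chromosome 18, from 50278369 to 50283020 in GRCm38 as annotated by GENCODE M21, a build given here from the reference annotation because the authors' build is not given in the sources used here. The part of the gene that was removed is not given either. The genotype label of KO replicate 2 names Fam171a where that of KO replicate 1 names Fam170a, and the count of 1 was the same in both. The paralogue Fam170b and 3 genes with names close to the second label did not pass the test. Fam170b had mean levels of 135 CPM in WT and 140 in KO, a log2 fold change of 0.06 (edgeR adjusted p = 0.717). The log2 fold changes were -0.60 for Fam171a1, 0.34 for Fam171a2 and -0.68 for Fam171b, with edgeR adjusted p of 0.249, 0.647 and 0.249.

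Beyond Fam170a, genes passed the test in both directions. Of 15636 genes tested, 71 were higher and 71 lower in KO at an adjusted p under 0.05, and 39 of the former and 58 of the latter, Fam170a among them, changed at least 2-fold. Among genes with a mean of at least 1 CPM and a symbol that is not a predicted or clone name, those that rose most were mostly low in WT, led by Cd5l, Slc22a22, Grtp1 and Gdf9, together with the better expressed Tubb6, Cdh2 and Plxnb2. Under the same limits the genes that fell most included Lrmda, the tropomyosin retrocopy Tpm3-rs7, the glutamate receptor Grm4, the integrin subunit Itgav and Piwil1, which encodes a PIWI protein that binds piRNAs in spermatocytes and round spermatids. At an unadjusted p under 0.05 there were 3846 genes. All 142 called genes kept their sign when any 1 library was left out, which says little of genes chosen for a difference between these libraries, and the number of calls moved widely. Such a fit also takes the spread from the other genotype's pair. With all libraries the number of calls was 1011 with DESeq2 and 451 without a filter on low counts.

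**Figure D1:**
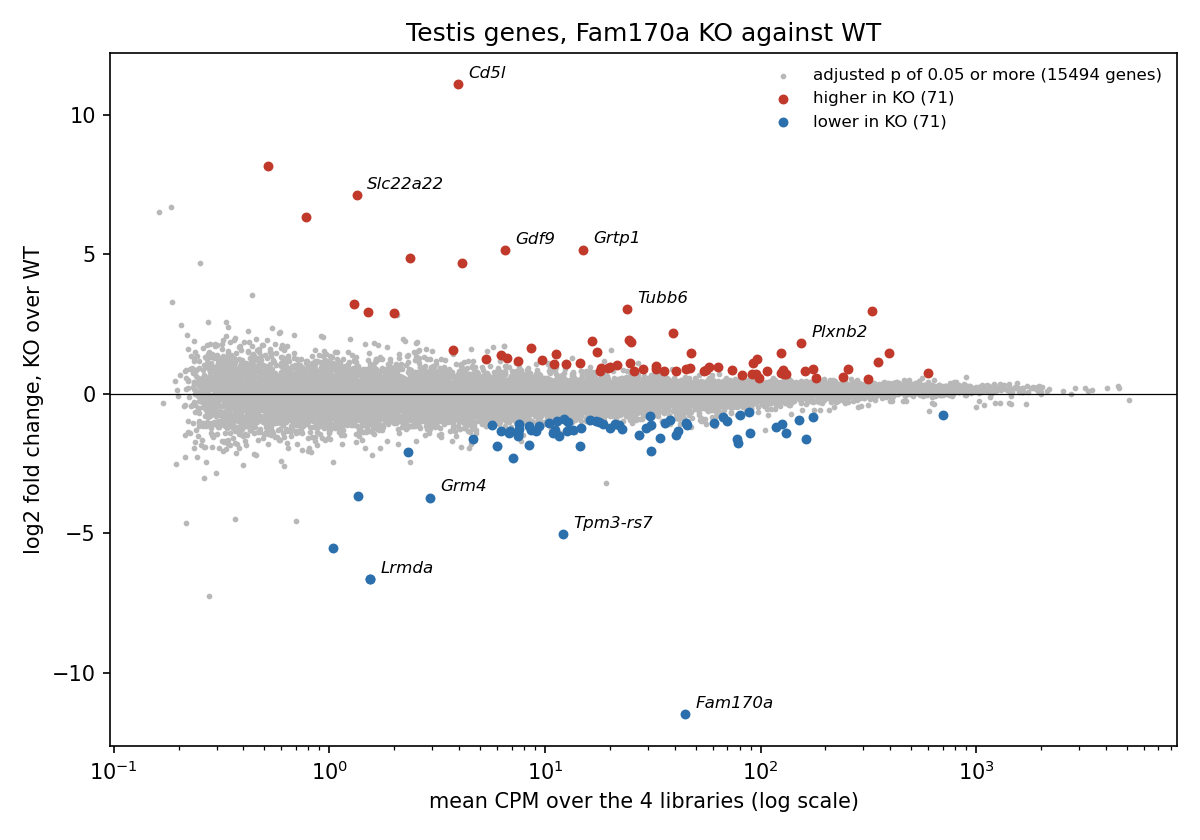
Each point is 1 of the 15636 tested genes, with its mean CPM over the 4 libraries on a log axis and its log2 fold change of KO over WT on the vertical axis. The 71 genes higher in KO (red) and the 71 lower (blue) passed an edgeR adjusted p of 0.05, and Fam170a lies lowest at -11.49.

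Among the 12 named genes with the largest rise, 2 were all but absent from WT. Cd5l, which encodes a scavenger receptor protein secreted by macrophages, had 0 counts in both WT libraries and 579 in the KO libraries together, at least 169-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00602). Slc22a22, an organic anion transporter gene, had 1 count in WT and 198 in KO, a ratio of 173 with a 95% counting interval of 30.7 to 6876. Grtp1, a gene for a TBC-domain protein, was at 0.779 ± 0.341 CPM in WT and 29.2 ± 0.247 in KO, a log2 fold change of 5.17 ± 0.25 (edgeR adjusted p = 0.00262). Gdf9, best known as a growth factor secreted by oocytes, was at 0.350 ± 0.0602 CPM in WT and 12.7 ± 0.479 in KO, a log2 fold change of 5.14 ± 0.21 (edgeR adjusted p = 0.00180). The neighbouring olfactory receptor genes Olfr1392 and Olfr1393 had log2 fold changes of 4.86 ± 0.32 and 3.20 ± 0.35. Tubb6, a beta-tubulin gene, rose from 5.27 ± 0.644 to 42.8 ± 3.16 CPM, and 2 cadherin genes rose with log2 fold changes of 2.92 ± 0.36 for Cdh26 and 2.19 ± 0.12 for Cdh2. Wdr49 had a log2 fold change of 2.90 ± 0.28 and the tropomyosin gene Tpm3 one of 1.84 ± 0.16. Plxnb2, a semaphorin receptor gene, rose from 68.3 ± 2.62 to 239 ± 7.64 CPM, a log2 fold change of 1.81 ± 0.08 (edgeR adjusted p = 0.00243).

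The 12 named genes with the largest fall had different known functions. Lrmda fell from 197 counts in WT to 2 in KO, a ratio of 113 with a 95% counting interval of 30.8 to 936. Tpm3-rs7 fell from 23.6 ± 0.312 to 0.718 ± 0.0670 CPM, a log2 fold change of -5.03 ± 0.16 (edgeR adjusted p = 0.000540). Log2 fold changes were -3.72 ± 0.28 for Grm4, a metabotropic glutamate receptor gene, -2.30 ± 0.22 for Itgav, -2.05 ± 0.21 for the deubiquitinase gene Stambp and -1.86 ± 0.13 for Rapgef2, which encodes an exchange factor for Rap GTPases. Adamtsl1 had a log2 fold change of -1.86 ± 0.16. Nckap1, a component of the WAVE complex that drives actin branching, fell from 122 ± 2.85 to 35.4 ± 1.70 CPM, and Ap1g1, a subunit of the clathrin adaptor AP-1, from 118 ± 9.35 to 38.5 ± 3.90 CPM. Piwil1 fell from 246 ± 21.8 to 80.4 ± 5.91 CPM, a log2 fold change of -1.61 ± 0.10 (edgeR adjusted p = 0.00713). Dut, which encodes the enzyme that breaks down dUTP, and the sulfotransferase gene Chst1 both had log2 fold changes of -1.53, with SE of 0.19 and 0.14.

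**Figure D2:**
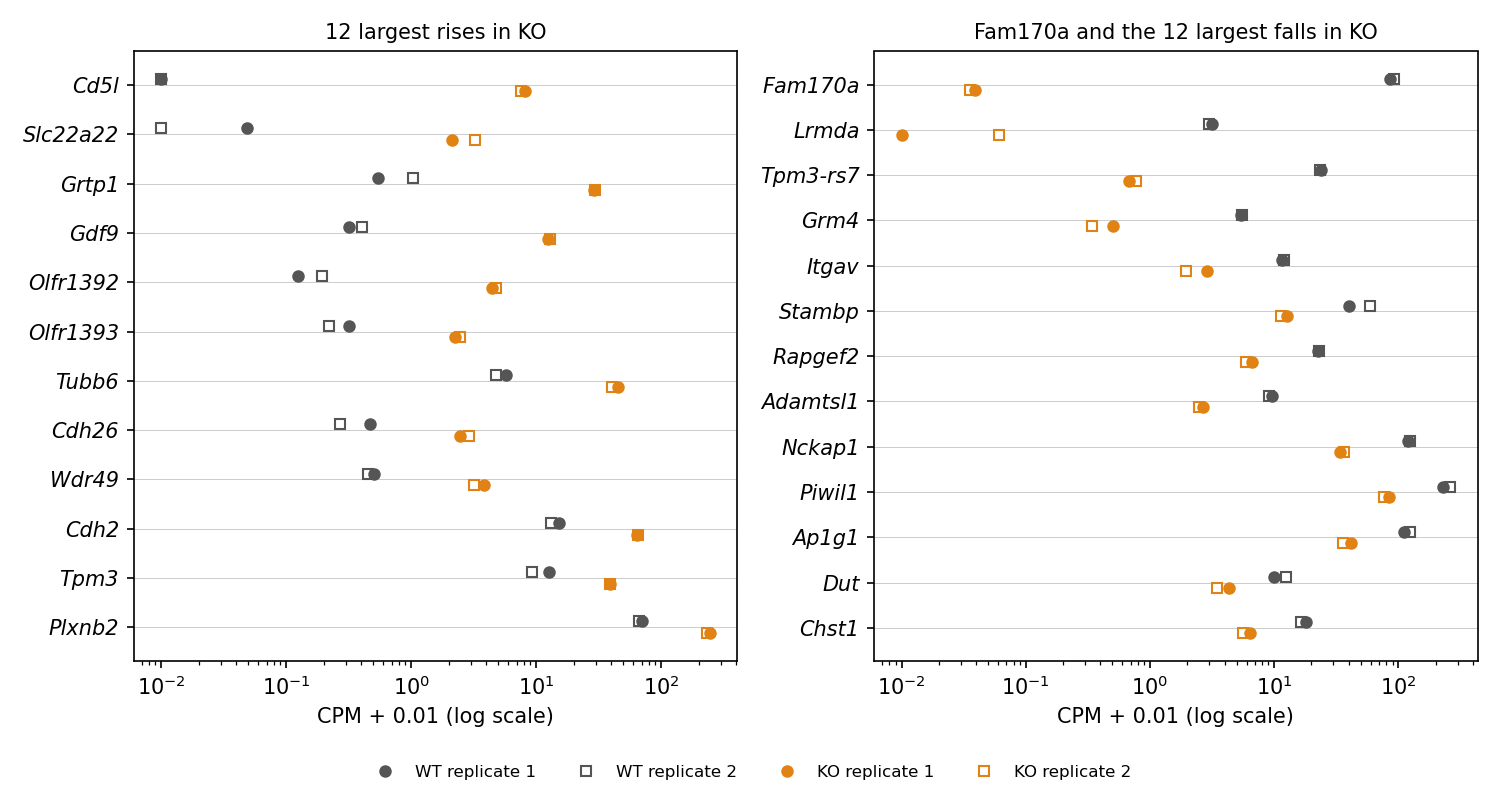
CPM of each library plus 0.01, on a log axis, for the 12 largest rises (left) and for Fam170a with the 12 largest falls (right). Grey symbols are the 2 WT libraries and orange symbols the 2 KO libraries, which do not overlap for any gene shown.

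Several of these values carry a limit of their own. Grtp1 overlaps Lamp1 on the opposite strand and Adamtsl1 overlaps Sh3gl2 on the same strand, and Slc22a22, Cdh2, Wdr49, Plxnb2, Lrmda, Grm4, Itgav, Stambp, Rapgef2, Nckap1, Piwil1 and Ap1g1 overlap annotated antisense, other noncoding or pseudogene transcripts. So do Id4, Spaca7, Slc2a3 and Catspere2 among the called genes below. Papolb, Pdilt and Insl3, named below but not called, overlap other coding genes, as does Fam171a2 above. Whether counting used strand is not given in the sources used here, so these levels are uncertain. Lamp1 itself had a log2 fold change of -0.07 (edgeR adjusted p = 0.633). Tpm3-rs7 is a retrocopy of Tpm3, and the olfactory receptor pair is also a set of closely related copies, so reads may have been split between them. Summed over Tpm3 and Tpm3-rs7, levels were 34.6 ± 2.65 CPM in WT and 39.7 ± 0.218 in KO, a log2 ratio of 0.20. Without KO replicate 1 the calls of Slc22a22, Olfr1393, Cdh26, Wdr49, Tpm3, Stambp, Rapgef2, Adamtsl1, Dut and Chst1 ended. Without KO replicate 2 the same 10 calls ended, as did those of Olfr1392, Lrmda, Grm4, Itgav, Piwil1 and Ap1g1. The call of Olfr1393 also ended with DESeq2 and that of Dut with scaling by total counts.

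Called genes lay on every autosome but chromosome 16, and on both sex chromosomes. The Y chromosome held 19 of the 71 higher genes and 0 of the lower ones among 132 tested (edgeR, with 77 higher and 1 lower at an unadjusted p under 0.05 and 48 higher by DESeq2 and 19 by limma-voom), and the X chromosome 1 higher gene among 677. Chromosome 2 held 10 lower genes and chromosome 14 held 9. Most Y genes belong to near-identical families, so their separate counts are uncertain. The number of Y genes called higher was 2 with scaling by total counts, 38 without a filter, 55 and 48 without WT replicate 1 and WT replicate 2, and 0 without either KO library, where 64 (without KO replicate 1) and 58 were higher at an unadjusted p under 0.05.

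**Figure D3:**
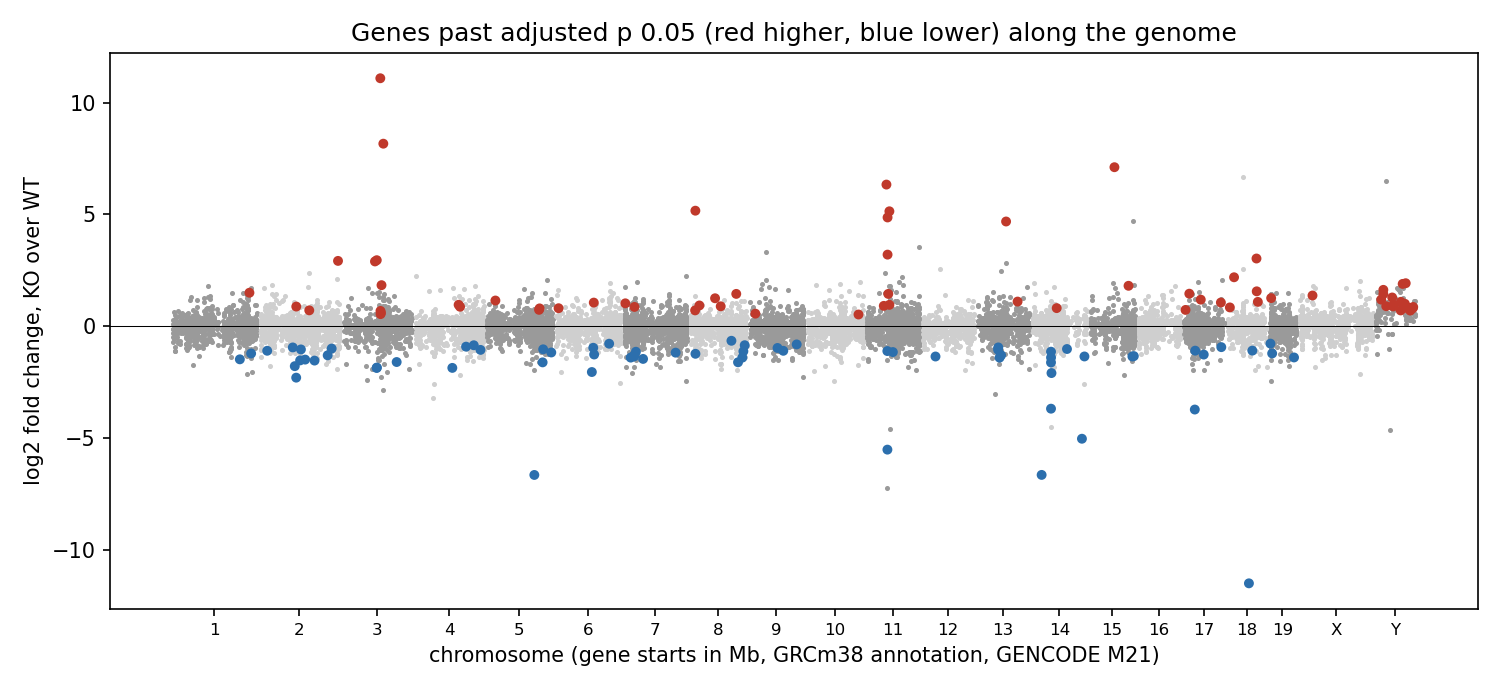
Log2 fold change of KO over WT of the tested genes by start position in Mb along chromosomes 1 to 19, X and Y of the GRCm38 annotation. Red points are genes higher and blue points genes lower in KO at an edgeR adjusted p under 0.05, and the 19 called genes on the Y chromosome all lie above 0.

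Markers of spermatogonia, the mitotic germ cells, were lower in KO as a list, while lists of later germ cell stages were mixed. Of 17 spermatogonial genes tested, 1 was lower and 0 higher, and 14 had negative fold changes around a median of -0.60. The set test gave a camera adjusted p of 0.00332, against an adjusted p = 0.789 with an estimated correlation between genes. The gene that passed was Id4, a transcription regulator of spermatogonial stem cells, at 14.1 ± 1.49 CPM in WT and 6.83 ± 0.529 in KO (log2 fold change -1.05 ± 0.15, with an edgeR adjusted p just under 0.05). Uchl1, Sall4 and Lin28a had log2 fold changes of -0.60, -1.02 and -0.72 without passing. Adjusted over the list alone, 2 members were lower. Without WT replicate 2 the list's median was -0.35 and its set test no longer passed. The early meiosis list, of 26 genes for synapsis and recombination, had no member past the edgeR test, with 2 higher and 8 lower at an unadjusted p under 0.05. DESeq2 called 1 higher and 5 lower, limma-voom called 0, and adjusted over the list alone 1 was higher. Its median was -0.22 (camera adjusted p = 0.124), with Hormad1 at -0.84 and the cohesin gene Rec8 at 0.51, and the set test passed, downward, without WT replicate 1 (median -0.43) and without KO replicate 1 (median -0.40), while the median was -0.05 without WT replicate 2 and -0.10 without KO replicate 2. Among 17 late spermatocyte genes 2 were lower, Piwil1 and Tdrd1, a piRNA pathway scaffold at 129 ± 14.8 CPM in WT and 49.0 ± 0.112 in KO (log2 fold change -1.39 ± 0.11). Adjusted over the list alone 1 was higher and 4 lower. That list's median of 0.11 was positive whereas its mean of -0.15 and its test, directed down with a camera adjusted p of 0.150, were negative. Without WT replicate 1 that test passed, still downward, at a median of 0.05, and the median was 0.07 without WT replicate 2, 0.17 without KO replicate 1 and 0.04 without KO replicate 2.

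A single regulator of round spermatids passed the test and no gene for RNA control in spermatids did. Of 18 round spermatid regulators 1 passed, Gmcl1, a gene required for nuclear and acrosomal shape, which fell from 92.6 ± 10.9 to 47.6 ± 1.31 CPM (log2 fold change -0.96 ± 0.11, edgeR adjusted p = 0.0320), and 1 was lower adjusted over the list alone. Crem, the activator of the postmeiotic program, was at 0.33 without passing, and the list's median was 0.14 (camera adjusted p = 0.264), or 0.23 with a set test that passed without WT replicate 1 and 0.06 without WT replicate 2. That set test also passed with limma-voom (0.0465). Of 17 genes for RNA control in spermatids none passed the edgeR test, while 4 were higher and 4 lower at an unadjusted p under 0.05. Adjusted over the list alone 2 were higher and 3 lower, DESeq2 called 1 higher and 2 lower, and limma-voom called 0. Piwil2 and Mov10l1 had log2 fold changes of -1.30 and -0.89, and the poly(A)-binding protein gene Pabpc2 and the poly(A) polymerase gene Papolb 0.37 and 0.31. The list's median was 0.08 against a mean of -0.13 and a test directed down (camera adjusted p = 0.825), and the median was just below 0 without WT replicate 1 and 0.04 without KO replicate 2.

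Of the 3 lists for chromatin compaction none passed the set test, and Piwil1 was the single gene that passed the edgeR test. Protamine and transition protein transcripts varied more between WT libraries than between genotypes, with Prm2 at 2587 and 693 CPM in the WT libraries and 855 and 1674 in the KO libraries. The 7 genes had a median of -0.14 (camera adjusted p = 0.958) and none passed, at an unadjusted p under 0.05, adjusted over the list alone, by DESeq2 or by limma-voom. Leaving out 1 WT library at a time moved the median between -0.75 and 0.68, with a set test that passed in opposite directions, and it was 0.14 without KO replicate 1 and -0.64 without KO replicate 2. Of 22 factors of histone-to-protamine exchange 1 was lower, Piwil1, and 1 was higher and 2 lower adjusted over the list alone. At an unadjusted p under 0.05, 3 of these factors were higher and 5 lower. DESeq2 called 1 of the factors higher and 4 lower, and limma-voom 1 lower. Their median of 0.12 differed in sign from their mean of -0.14 and from the test, directed down (camera adjusted p = 0.432), and it was 0.08 without WT replicate 1, 0.02 without WT replicate 2 and 0.06 without KO replicate 2. The 9 tested histone variants of the testis had a median of 0.09 (camera adjusted p = 0.363) and none passed the edgeR test, nor adjusted over the list alone, with 1 higher at an unadjusted p under 0.05 and 0 called by DESeq2 and limma-voom. Their median was 0.68 with a set test that passed without WT replicate 1, -0.36 without WT replicate 2, 0.25 without KO replicate 1 and -0.15 without KO replicate 2.

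Of the lists for sperm structure and function, 4 passed the set test upward with small medians and 4 did not pass. The axoneme list had a median of 0.21 over 33 genes, of which 30 were positive (camera adjusted p = 0.000437, and adjusted p = 0.789 with an estimated correlation). Medians were 0.21 for 25 acrosome genes (camera adjusted p = 0.00256), 0.20 for 23 ion channel and motility signalling genes (camera adjusted p = 0.00340) and 0.21 for 20 genes of sperm-egg interaction (camera adjusted p = 0.0446), each with an adjusted p = 0.789 with an estimated correlation. The single gene tested in these 4 lists that passed the edgeR test was Spaca7, an acrosomal protein gene that rose from 99.4 ± 0.517 to 162 ± 10.4 CPM (log2 fold change 0.71 ± 0.08, edgeR adjusted p = 0.0341). Catspere2, given as another name in the list entry that was resolved to Catspere1, was not tested with the list and passed on its own, at means of 9.08 CPM in WT and 25.7 in KO (edgeR adjusted p = 0.0122), while Catspere1 was at -0.28. How reads that match both genes were counted is not given, so the separate levels of this pair are uncertain. Examples that did not pass were Cfap58 at 0.40, Catsper1 at 0.36 and Pdilt, a chaperone of sperm surface proteins, at 0.38, while Tex101 was at -1.14. Adjusted over the list alone, 7 axoneme genes were higher and 0 lower, 7 acrosome genes higher and 1 lower, 9 ion channel genes higher and 0 lower, and 2 sperm-egg genes higher and 1 lower. With no axoneme call by edgeR, 19 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 4 higher and limma-voom 0. For ion channels these counts were 12 higher and 1 lower, then 1 higher by DESeq2 and 0 by limma-voom, and for sperm-egg interaction 7 higher and 1 lower, then 1 higher and 1 lower by DESeq2 and 0 by limma-voom. For the acrosome they were 13 higher and 1 lower, then 4 higher and 1 lower by DESeq2 and 1 higher by limma-voom. With scaling by total counts, which lowered the median of all tested genes from 0.01 to -0.10, the medians of these 4 lists lay between 0.09 and 0.11. The call for sperm-egg interaction ended there, with the filter at 1 CPM and without WT replicate 2, KO replicate 1 or KO replicate 2.

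The remaining lists of sperm assembly did not pass the set test. The fibrous sheath and outer dense fibre list had a median of 0.11 over 24 genes (camera adjusted p = 0.0567) and the head shaping and manchette list 0.10 over 27 (camera adjusted p = 0.124). Neither had a call by edgeR or adjusted over the list alone. The fibrous sheath list passed with DESeq2 size factors in edgeR, upper quartile factors, no filter, DESeq2 and limma-voom (adjusted p from 0.00736 to 0.0487), and the head shaping list with limma-voom (0.0167). Both set tests passed without WT replicate 1, at medians of 0.26 and 0.18, and that of the fibrous sheath list also without KO replicate 1, at 0.22, while its median was -0.06 without WT replicate 2 and 0.01 without KO replicate 2. The head shaping median was 0.19 without KO replicate 1 and 0.06 without KO replicate 2. At an unadjusted p under 0.05, 7 fibrous sheath genes were higher and 0 lower, and 7 head shaping genes were higher and 1 lower. DESeq2 called 1 fibrous sheath gene higher and 1 head shaping gene lower, and limma-voom called 0 in both. Cntrob, a centrosomal gene needed to attach the head to the tail, was at -1.38 without passing. The ubiquitin and cytoplasm removal list had a median of 0.10 over 19 genes (camera adjusted p = 0.274) and no call, with 4 higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 1 higher and 1 lower there and limma-voom 0, and adjusted over the list alone 1 was lower. Its set test passed without WT replicate 1 (median 0.24), and its median was -0.07 without WT replicate 2 and 0.20 without KO replicate 1. In the sperm energy list 1 of 22 genes passed, the glucose transporter gene Slc2a3, which fell from 891 ± 73.2 to 519 ± 35.9 CPM (log2 fold change -0.78 ± 0.10, edgeR adjusted p = 0.0368) and was also the 1 gene lower adjusted over the list alone. That list's median was 0.08, its mean -0.01 and its test directed up (camera adjusted p = 0.888), and its median was -0.02 with scaling by total counts, 0.18 and -0.07 without WT replicate 1 and WT replicate 2, 0.15 without KO replicate 1 and near 0 without KO replicate 2. The medians of the RNA control, head shaping and testis histone lists also turned negative under that scaling, at -0.03, -0.005 and -0.01.

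**Figure D4:**
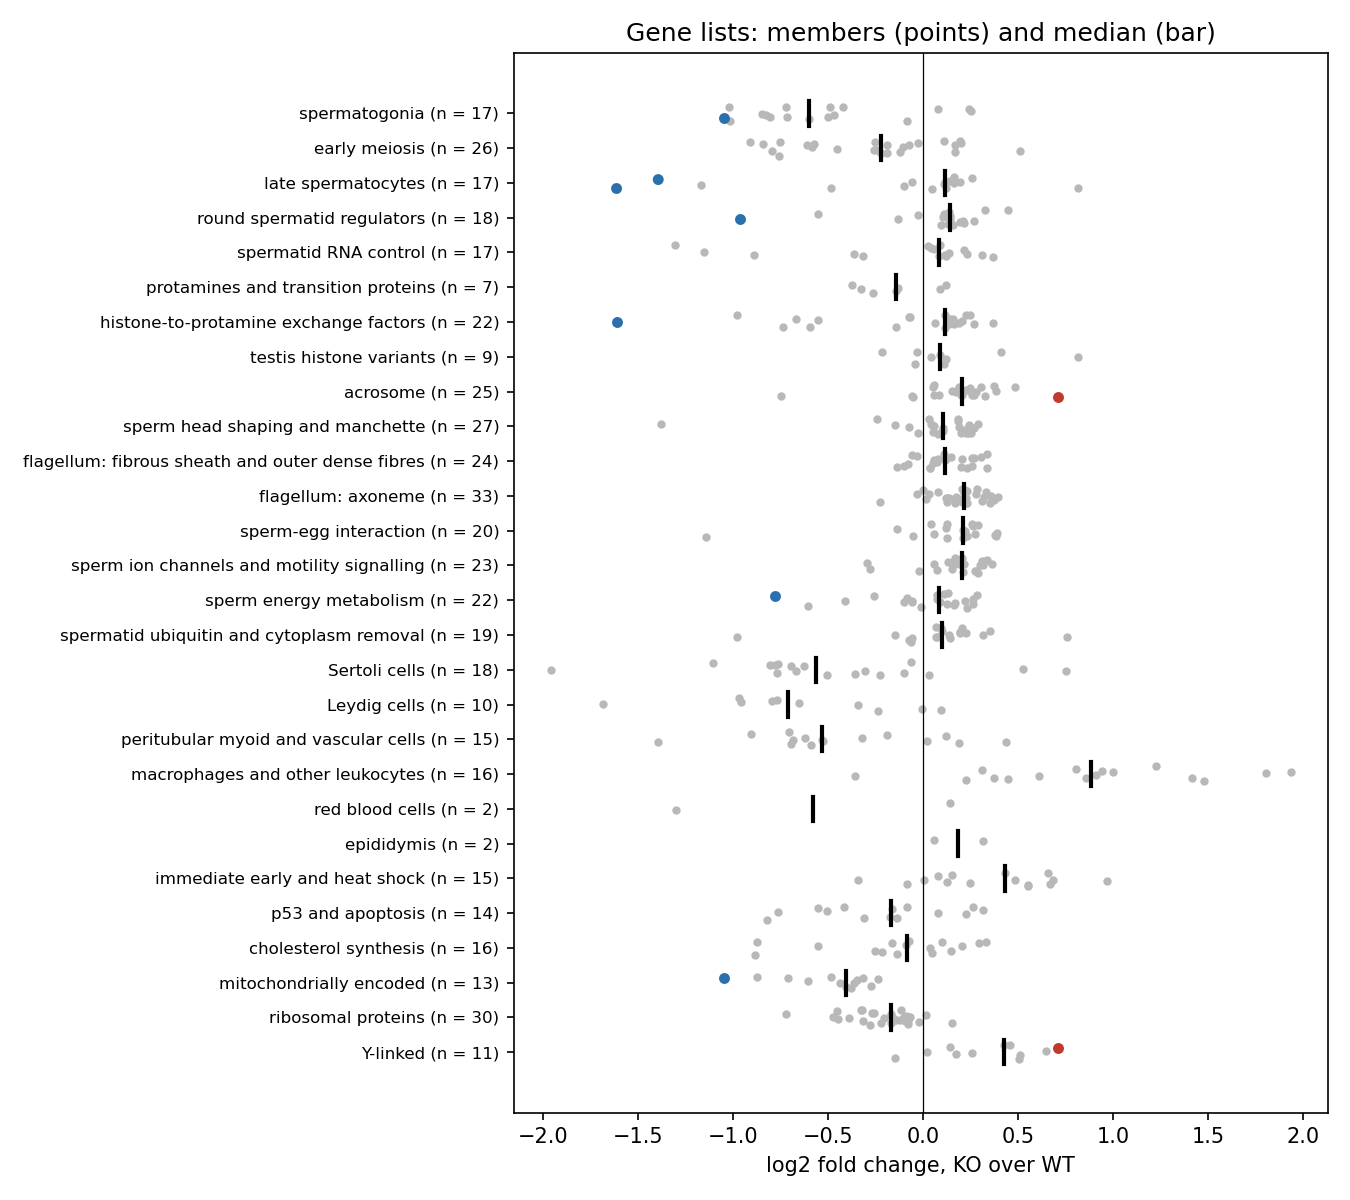
Log2 fold change of KO over WT of the tested members of each of the 28 gene lists (points, spread vertically for legibility) and the list's median (black bar). Members past an edgeR adjusted p of 0.05 are red (higher) or blue (lower), and the number of tested members stands after each list's name.

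Somatic cell markers were sparse in all libraries and depended on single libraries. Sertoli cell genes had a median log2 fold change of -0.56 over 18 genes (camera adjusted p = 0.0369, and adjusted p = 0.789 with an estimated correlation), with Clu at 48.8 ± 28.0 CPM in WT and 22.6 ± 4.32 in KO. That median was 0.05 without WT replicate 1 and -0.37 without KO replicate 1, neither with a set test that passed, and -0.95 without WT replicate 2, and the call also ended with scaling by total counts. Leydig cell genes had a median of -0.71 over 10 genes (camera adjusted p = 0.124), and Insl3, their secreted hormone, was at 3.87 ± 2.18 CPM in WT and 1.19 ± 0.0542 in KO. With limma-voom the Leydig median was -0.31, and with the filter at 1 CPM it was -0.44. The Leydig median was 0.24 without WT replicate 1, and -1.22 with a set test that passed without WT replicate 2. Peritubular myoid and vascular genes had a median of -0.53 over 15 genes (camera adjusted p = 0.0933), or -0.42 with a set test that passed without KO replicate 2, and -0.35 and -0.31 without WT replicate 2 and KO replicate 1. That set test also passed with limma-voom (0.0496). Leukocyte genes went the other way, with a median of 0.88 over 16 genes (camera adjusted p = 0.00409, and adjusted p = 0.789 with an estimated correlation). Their median level was 2.67 CPM in WT replicate 1 and 0.405 in WT replicate 2, against 3.78 and 2.28 in the KO libraries, and without WT replicate 2 the median fold change was 0.15 and the set test did not pass. It was 2.30 without WT replicate 1 and 0.39 without KO replicate 1. No gene of these 4 lists passed the edgeR test or passed adjusted over the list alone. At an unadjusted p under 0.05, 3 Sertoli, 2 Leydig and 5 myoid or vascular genes were lower and 2 leukocyte genes were higher, and DESeq2 called 1 Sertoli and 1 Leydig gene lower and limma-voom 0. Of 7 red blood cell genes and 12 epididymal genes only 2 of each were tested, with medians of -0.58 and 0.19, camera adjusted p of 0.877 and 0.687, and no call by edgeR, adjusted over the list alone, by DESeq2, by limma-voom or at an unadjusted p under 0.05. The former median was -0.04 and -0.97 without WT replicate 1 and WT replicate 2, and the latter 0.08 without WT replicate 1, 0.31 without KO replicate 1 and 0.04 without KO replicate 2.

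Transcripts encoded by mitochondrial DNA were lower in KO throughout. All 13 had negative fold changes, with a median of -0.41 (camera adjusted p = 1.13e-07, and adjusted p = 0.789 with an estimated correlation). Of these mt-Nd3 passed, falling from a mean of 82.1 to 39.7 CPM (log2 fold change -1.05 ± 0.12, edgeR adjusted p = 0.0338), and all 13 were lower adjusted over the list alone, while DESeq2 called 11 lower and limma-voom 2. Mitochondrial counts made up 1.60% and 1.67% of the WT libraries and 1.26% and 1.14% of the KO libraries. The ribosomal protein list had a median of -0.17 over 30 genes, of which 28 were negative (camera adjusted p = 0.00350, and adjusted p = 0.789 with an estimated correlation). None of these 30 passed the edgeR test or passed adjusted over the list alone, with 9 lower at an unadjusted p under 0.05, 2 lower by DESeq2 and 0 by limma-voom, and without KO replicate 1 the set test did not pass. Rpl10a, a ribosomal protein gene outside the list, was called lower (log2 fold change -1.09, edgeR adjusted p = 0.0276). Y-linked genes had a median of 0.43 over 11 genes, or 0.23 without WT replicate 1, and 10 were positive (camera adjusted p = 0.00335, and adjusted p = 0.789 with an estimated correlation). The spermatid gene Sly rose from 72.4 ± 0.456 to 118 ± 3.89 CPM (log2 fold change 0.71 ± 0.08, edgeR adjusted p = 0.0320), and 4 of the list were higher adjusted over the list alone.

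The stress and metabolic lists did not pass the set test. Immediate early and heat shock genes had a median of 0.43 over 15 genes (camera adjusted p = 0.124), p53 and apoptosis genes -0.17 over 14 (camera adjusted p = 0.354) and cholesterol synthesis genes -0.08 over 16 (camera adjusted p = 0.687). With limma-voom the immediate early median was 0.17. No member of these lists passed the edgeR test. At an unadjusted p under 0.05, 1 immediate early gene was higher, 3 p53 genes were lower, and 2 cholesterol genes were higher and 3 lower, while DESeq2 called 1 p53 gene lower and limma-voom 0. Adjusted over the list alone, 2 cholesterol genes were higher and 2 lower, and 0 of the other 2 lists. The immediate early list passed the set test without WT replicate 1 and without KO replicate 2, with medians of 0.38 and 0.76, but not without WT replicate 2 or KO replicate 1, with medians of 0.10 and 0.11. The p53 median was -0.41 without WT replicate 1 and 0.04 without WT replicate 2, and the cholesterol median -0.05 without KO replicate 2.

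The calls of genes within lists mostly ended when a KO library was left out and the spread came from the WT pair alone. Without KO replicate 2 those of Id4, Piwil1, Tdrd1, Gmcl1, Spaca7, Slc2a3, Sly and mt-Nd3 all ended, and without KO replicate 1 all of them but that of Piwil1 ended. Id4 also missed the threshold with either other scaling of the counts, with scaling by total counts, with a filter at 1 CPM and with limma-voom, and with total-count scaling Spaca7 and Sly missed it too. No list passed the fry test, which asks whether a list's genes move one way on balance (lowest adjusted p = 0.0984). Its mixed form, which asks for changes in either direction, passed for 6 lists: late spermatocytes, ion channels, mitochondrially encoded and Y-linked genes (each with an adjusted p of 0.0429), cholesterol synthesis (0.0435) and the axoneme (0.0455).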

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

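All alternatives reported here were chosen before the data were examined, except the counts of Y chromosome genes given under other observations. The log2 fold change of Fam170a stayed between -11.69 and -11.09 and past the threshold in every alternative, and all 142 called genes kept their sign in every alternative that tested them, as genes chosen for a difference between these libraries are apt to do. Of those calls 107 were also made with DESeq2 size factors in edgeR, 125 with upper quartile factors, 80 with total counts, 142 without a filter, 137 with the 1 CPM filter, 138 with DESeq2, 132 with limma-voom, 142 without either WT library, 20 without KO replicate 1 and 11 without KO replicate 2. The counts of calls were far less stable. Scaling by total counts gave 32 genes higher, 24 of them at least 2-fold, and 39.0% of its calls were higher against 50% with TMM. Without a filter 171 genes were higher and 280 lower, 60 and 140 at least 2-fold, and 37.9% of the calls were higher. DESeq2 gave 383 higher and 628 lower, 64 and 184 at least 2-fold. A threshold of 0.01 left 11 higher and 7 lower, all of them at least 2-fold. Leaving out each library in turn gave 8 to 1264 genes higher and 3 to 1936 lower, and 8 to 244 and 3 to 591 at least 2-fold. The fewest came without a KO library, when the spread is taken from the WT pair, which differed more than the KO pair, and the most without a WT library. The cause of the other differences was not tested. The median of the protamine list reversed, with values from -0.75 to 0.68 as each library was left out, the highest without WT replicate 1. A block on the replicate number left 6 genes higher and 3 lower, all at least 2-fold and all among the 142, but deviations of same-numbered libraries had a correlation across 13161 genes of -0.29, so the numbers are not taken to pair the samples. With 2 libraries per genotype, opposite-numbered libraries have the same value with a positive sign. They therefore shared some variation across genotypes, which was not modelled. At this depth and with 2 libraries per genotype, edgeR recovered 75% of simulated 2-fold changes, so smaller changes were often beyond reach. That simulation left out low counts among the changed genes and any spread of a single gene, so the share may differ in the data. Its edgeR and DESeq2 recoveries were close, whereas in the data edgeR called 142 genes and DESeq2 1011.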

Other observations

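The tests in this part were not planned and concern patterns first seen in these data. Those of X-linked families, GC content and transcript length were chosen before their own values were seen, and the others after. Genes named here outside the lists were chosen after their values were seen.

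Several genes of the piRNA pathway, which silences transposons in the male germ line, fell in KO. Beside Piwil1 and Tdrd1 these were Tdrd5, from 59.5 ± 3.32 to 21.4 ± 5.27 CPM (log2 fold change -1.48 ± 0.18, edgeR adjusted p = 0.0350), and Adad2, from 10.9 ± 0.366 to 4.14 ± 0.0440 CPM (log2 fold change -1.40 ± 0.14, edgeR adjusted p = 0.0235). Of 25 pathway genes tested, 4 were lower and 19 had negative fold changes. The 25 include the genes first noticed as low, which were Piwil1, Piwil2, Tdrd1, Tdrd5, Mov10l1 and Adad2. Of the 19 pathway genes without those, 0 were called and 13 had negative fold changes. Single genes that rose included Armc4, needed to dock outer dynein arms, from means of 91.5 to 164 CPM, the dynein intermediate chain gene Wdr78 from 124 ± 3.55 to 227 ± 10.7 CPM, and Catspere2 from 9.08 ± 0.512 to 25.7 ± 0.537 CPM. Catspere1, named in the same list entry as Catspere2, had a negative fold change, and reads may have been split between them. Among genes with predicted or clone names, Gm17359 rose from 74.8 ± 2.54 to 580 ± 29.5 CPM (log2 fold change 2.95 ± 0.09, edgeR adjusted p = 0.000540), a level made uncertain by Fnip2 on the opposite strand (log2 fold change -0.29), and overlaps of the other genes named in this paragraph and not in the lists were looked up for Catspere2 alone. Gm5286 had 0 counts in WT and 76 in KO, at least 22.2-fold higher against 3 counts over the group, and Gm15446 had 203 counts in WT and 2 in KO. All 142 calls, these included, were also made without a filter and without either WT library, but 20 and 11 of the 142 without KO replicate 1 and KO replicate 2.

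Genes of the multicopy families on the Y chromosome, which are transcribed in spermatids, were higher in KO. Of 132 Y genes tested 19 were higher and 0 lower (edgeR, with 77 higher and 1 lower at an unadjusted p under 0.05, and 0 lower by DESeq2 or limma-voom), against 52 higher genes elsewhere (two-sided Fisher's exact test p = 6.29e-24, over genes that share sequence and are not independent). Counts summed over the 121 family genes were 1038 ± 42.5 CPM in WT and 1810 ± 114 in KO, a log2 ratio of 0.80, so reads moved among these copies alone do not account for the rise. The acrosome, axoneme and fibrous sheath lists together had a median of 0.20 over 82 genes and X-linked spermatid families one of 0.15 over 25 genes. Both lay below the Y family median of 0.71. That argues against a larger share of spermatids or a rise of sex-linked families in general as the whole explanation. The interquartile range was -0.17 to 0.61 for the X families and 0.46 to 0.97 for the Y families, so some X families may have risen too. The 1 call among these X families, Spin2e (log2 fold change 1.38), was the only call on the X chromosome. A different Y chromosome in the KO mice cannot be told apart from an effect of genotype, since no value names the strain, and 8 single-copy Y genes had a median of 0.21. The number of Y genes called higher was 2 with scaling by total counts, 38 without a filter, 48 with DESeq2, 55 and 48 without WT replicate 1 and WT replicate 2, and 0 without either KO library, where 64 and 58 were higher at an unadjusted p under 0.05.

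Some called genes lay close together, as Cd5l, Lrrc71, Hdgf, Gon4l and Tpm3 do on chromosome 3 and Uqcrq and Gdf9 on chromosome 11, and segments of another strain carried by one genotype may leave such groups. Over all 100 autosomal calls left after genes with predicted, clone or olfactory receptor names were set aside, which leaves out the neighbours Olfr1392 and Olfr1393, 31 had another within 2 Mb, against a median of 25 and an upper bound of 36 (the end of the central 95%) in 10000 random sets matched on expression (permutation p = 0.153), and by the rule first written, in which the bound was to exceed 95% of the random sets, this number counted against such segments. That rule was reworded after the number was seen, and a number between the median and the bound is now read as undecided. The calls were then split by direction because of that result, and 13 of 42 higher genes had a higher neighbour against a median of 4 (permutation p = 0.00730), while 8 of 58 lower genes had a lower one against a median of 9 (permutation p = 0.665), so the excess among higher genes is 1 of 3 looks at the same data. The names set aside included Gm8126, Gm9732, Gm8127 and 1700001F09Rik, all lower, which start between 43258649 and 43342383 on chromosome 14. The count of lower genes therefore leaves out a close group and does not show that lower genes lie apart. A segment within 10 Mb of the targeted gene does not account for the pattern as a whole, since 1 of 65 tested genes there was called (Fisher's exact test p = 0.446). Over chromosome 18 without Fam170a, 6 of 397 tested genes were called. Among them were Tubb6 and Ldlrad4, which start at 67390717 and 67933257 and belong to the 13 higher genes with a neighbour. A longer segment was not tested. With Fam170a itself left out, 2 of 23 called autosomal genes changed at least 4-fold lay on chromosome 18. Of these 23, 5 lay on chromosome 11 between 40 and 65 Mb, where 10 of 220 tested genes were called (a span chosen after it was seen). Strain segments beyond 10 Mb from Fam170a and co-regulated neighbours both stay open.

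The genes lower in KO had a median log2 fold change of -1.28 over 70 genes without Fam170a, and a smaller share of spermatocytes, a bias of GC content or length, or a shared fall of the piRNA pathway could each give such a group. The late spermatocyte list had a median of 0.11, well above that of the lower genes, with 11 of 17 genes positive. Its mean of -0.15 includes Piwil1 and Tdrd1, which are themselves among the lower genes, so that mean does not bear on the question. The early meiosis list had a median of -0.22 with 20 of 26 genes negative, so a smaller share of spermatocytes is not excluded as a part of the fall. Removing the trend of fold change on transcript GC content left the lower genes at -1.23, and removing that on length left them at -1.25, but the trends themselves ran only from -0.06 to 0.03 and from -0.06 to 0.04 over the central genes, so these corrections had little to remove and show only that such trends across all genes were small. The 19 piRNA pathway genes other than those first noticed had a median of -0.27 with 0 called by edgeR or limma-voom, 2 lower by DESeq2, and 1 higher and 7 lower at an unadjusted p under 0.05. Their camera p was 0.0190, and p = 0.435 with an estimated correlation, which leaves a shared fall of the pathway open.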
